A study of Arabidopsis thaliana with 18 samples.

How the data were processed

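RNA sequencing libraries came from whole seedlings of Arabidopsis thaliana, 3 for each of 6 groups formed by 2 genotypes and 3 treatments, and groups were taken from the sample labels. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were run on TAIR10, without versions or settings. The deposited table holds 1 value per group made by the authors from the 3 libraries, taken here as FPKM because these tools write that unit, although the header does not name it. The authors also deposited log2 ratios of treated over control, which equalled the ratios of the group values within 4.7e-05, so no pseudocount had been added, and a yes or no call for each comparison. The rule behind the calls is not stated. All called genes but 1 were at least 2-fold apart, and 312, 228, 201 and 227 genes at least 2-fold apart were not called for wild-type ABA, wild-type mannitol, duodecuple ABA and duodecuple mannitol, most of them at low values. Of these 15, 14, 4 and 18 reached 5 FPKM. Cells with a spreadsheet error (151) stood where the treated value was 0, and 166 cells held infinity where the control was 0. Neither p-values nor values or depths per library are in these files, so no replicate error, interval or detection limit could be given, and the precision of each value is unknown.

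The table lists 6740 genes, each called at least once among the 4 comparisons, so genes without any call were not analysed here, and a share of the table is not a share of the genome. For 6726 genes the identifier matched a reference gene table of assembly TAIR10.1, which was used for symbols and gene order; its coordinates were not used here. The other tables, 2 selected lists of genes called under mannitol in the duodecuple line alone, repeat the full table in 22 columns and were used for membership.

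The planned models need values per library and could not be fitted, so the authors' calls and ratios are described as deposited and no test was run on genes. Counts adjusted over the list alone could not be given either. A change is a call with the sign of the ratio. Levels of the genotypes, and the difference between their responses, which carry no authors' call, are ratios of group values counted at 2-fold or more where the higher group had at least 5 FPKM, and are untested. The set of genes 4-fold apart in all 3 treatments, and the one 4-fold apart in control seedlings, needed 1 FPKM or more in the higher group instead. Overlaps are counts of genes called in the same direction, without Fisher's test because the table holds called genes only, and the effect of the shared wild-type control on the ABA and mannitol overlap could not be simulated. Values of 0 are given as listed at 0 without a fold, and infinite ratios took the end of the ranking in medians. Correlations are across genes.

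The rule for named genes took, for each treatment comparison, the 10 largest rises and 10 largest falls among called genes with at least 5 FPKM in the higher group. For genotype ratios, overlaps and response differences it took the 5 largest per direction, and it added up to 4 members of each gene list, chosen by fold since no p-values exist, and all listed receptors, clade A phosphatases, SnRK2 kinases and reference genes. Some list members named in the text beyond these 4, and single members named to illustrate a group, were chosen after the values were seen. The 26 gene lists hold 350 genes, 244 of them in the table, and 3 extra lists were added after the largest differences had been seen, for phosphate starvation, root tissue other than hairs, and the root hair part of a fixed list. Each list is given as its members called higher, lower or not called, with the median log2 ratio of listed members. As a description, medians were placed among those of 10000 random lists of table genes matched in 10 bins of expression, for lists of at least 5 members.

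Intervals of marker medians are percentile bootstraps over genes (10000 resamples, 95%). Clustering of genes along chromosomes was compared with circular shifts of labels along the gene order, with a window of 100 annotated loci. The list placement and the shift procedure were tested on simulated data. Of 40 shifted lists 100% were placed outside the central 95% of random lists, against 5% of 100 unchanged ones. All members of a shifted list moved by the same large amount over independent noise. The power for smaller shifts, or for lists whose genes move together, was not measured. A planted cluster was matched by 0.534% of shifts and an unplanted one by 33.5%. Unchanged lists were random draws themselves, and the planted cluster lay at a single locus. The power of the pooled count over 11 loci is therefore unknown. Alternatives were a minimum of 5 FPKM, pseudocounts of 0.1, 1 and 5 FPKM, a 4-fold limit and no minimum, each against the main choice. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.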

Results

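Transcripts were sequenced from 9-day-old seedlings of 2 Arabidopsis thaliana genotypes, the Col-0 wild type and a duodecuple line carrying mutations in 12 genes for PYR/PYL receptors, the proteins that bind the stress hormone abscisic acid (ABA). Both were kept for 24 h on filter paper with medium alone (control), with 100 µM ABA, or with 300 mM mannitol, a sugar alcohol that imposes osmotic stress. Each of the 6 groups held 3 samples, 18 in all. The deposited table gives 1 expression value per group, in FPKM (sequenced fragments scaled to transcript length and library size, a unit inferred from the tools used), so no value has a replicate error, and the depth of the samples is unknown. It lists 6740 genes, each called as changed by the authors in at least 1 of the 4 comparisons of a treatment with its control; genes outside it were not analysed here. Gene lists are counted over their listed members, 244 of 350 genes. Of 16 ABA metabolism genes 8 are listed, and of 16 osmolyte genes 10. Members without any call are absent, so such shares overstate those of the whole lists. A rise or a fall always means an authors' call, and ratios between the genotypes, which carry no call, are given as values that were not tested. Loci are named by their TAIR10 identifiers, and chromosome coordinates were not used here.

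Among the receptor genes themselves, 5 of the 12 mutated ones were listed, of which 3 fell under ABA and 4 under mannitol in the wild type. PYL4 (AT2G38310) fell 4.93-fold under ABA and 3.63-fold under mannitol, PYL5 (AT5G05440) fell 3.49-fold and 3.56-fold, and PYL8 (AT5G53160) fell 2.31-fold and 2.87-fold. PYR1 (AT4G17870) fell under mannitol from 173 to 80.1 FPKM and stood at 111 FPKM under ABA without a call. In the duodecuple line none of these 4 was called under either treatment. In its control seedlings PYR1 was listed at 181 FPKM, PYL4 at 112, PYL8 at 73.0 against 225 in the wild type, and PYL5 at 13.1 against 90.6. PYL12 (AT5G45870) was listed at 0.407 FPKM in the wild-type control and at 1.57 FPKM in the duodecuple control, had no call in the wild type, and was called lower in the duodecuple line under mannitol, where it was listed at 0. PYL6 (AT2G40330), a family member that the title does not count among the mutated genes, fell 38.8-fold under ABA and 20.5-fold under mannitol in the wild type. In the duodecuple line PYL6 was not called, with 58.1 FPKM in control, 56.9 under ABA and 39.97 under mannitol. These are transcript levels per gene and do not show whether a transcript carries a lesion.

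Wild-type seedlings on ABA raised the hormone's known target genes and lowered all listed mitotic and most listed cytokinin response genes. This comparison answers what ABA does where the receptors are intact. The authors called 1185 genes higher and 1839 lower, with median log2 ratios of 1.63 and -1.59. All 18 listed genes for ABA- and dehydration-responsive proteins rose, with a median log2 ratio of 4.26. Among them LEA7 (AT1G52690), a late embryogenesis abundant protein, rose 236-fold to 1305 FPKM, LEA4-5 (AT5G06760) rose 167-fold, and the dehydrin RAB18 (AT5G66400) rose 76.3-fold from 20.4 to 1554 FPKM.

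**Figure D1:**
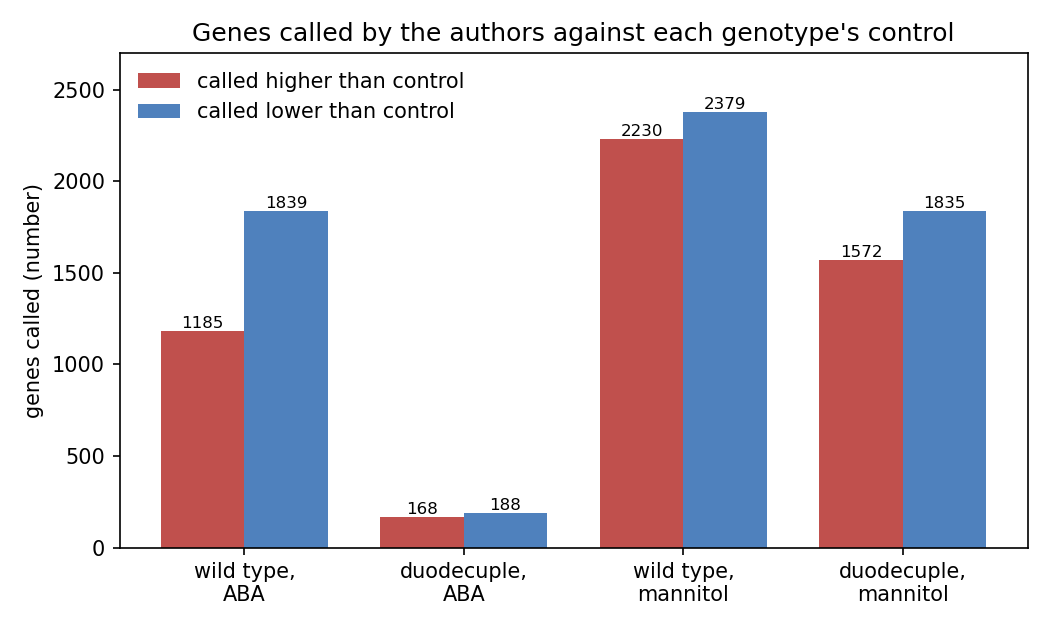
Number of genes the authors called higher (red) or lower (blue) than the control of the same genotype, for each of the 4 treatment comparisons. Under ABA 1185 and 1839 genes were called in the wild type against 168 and 188 in the duodecuple line, and under mannitol 2230 and 2379 against 1572 and 1835.

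The core signalling genes of the wild type moved with them. All 7 listed clade A PP2C phosphatases, which hold the ABA pathway off, rose under ABA, from ABI1 (AT4G26080) at 3.89-fold and PP2CA (AT3G11410) at 4.47-fold to HAI2 (AT1G07430) at 86.3-fold and HAI3 (AT2G29380) at 434-fold; HAB1 (AT1G72770), ABI2 (AT5G57050) and HAI1 (AT5G59220) reached 71.1, 48.0 and 97.8 FPKM. Of 6 listed SnRK2 kinases, which the phosphatases restrain, SNRK2.6 (AT4G33950) rose 2.99-fold, SNRK2.7 (AT4G40010) 5.21-fold and SNRK2.9 (AT2G23030) 2.24-fold, while SNRK2.5 (AT5G63650) fell 2.63-fold and SNRK2.8 (AT1G78290) fell 2.26-fold. SNRK2.3 (AT5G66880) was not called, at 33.9 FPKM in control and 42.5 under ABA. Of 7 listed ABA-responsive transcription factors 6 rose, among them MYB102 (AT4G21440) 19.7-fold, HB7 (AT2G46680) 12.1-fold and HB12 (AT3G61890) 9.22-fold. ABI5 (AT2G36270) was 1.90-fold higher and not called. In ABA metabolism 6 of 8 listed genes rose and 1 fell. The ABA-degrading hydroxylases CYP707A1 (AT4G19230) and CYP707A2 (AT2G29090) rose 19.9-fold and 6.98-fold, NCED3 (AT3G14440), which makes the precursor of ABA, rose 3.69-fold, and the ABA importer gene ABCG40 (AT1G15520) fell 2.34-fold.

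Osmolyte, chaperone and pigment genes also rose in ABA-treated wild-type seedlings. In proline and osmolyte metabolism 7 of 10 rose, with P5CS1 (AT2G39800), the key proline synthesis gene, going from 37.0 to 226 FPKM and the galactinol synthase gene GOLS2 (AT1G56600) rising 8.77-fold. Of 11 heat shock genes 10 rose, among them HSP22 (AT4G10250) 426-fold, HSP17.4 (AT3G46230) 71.5-fold and HSFA2 (AT2G26150) 28.5-fold, and HSFA3 (AT5G03720) fell 6.37-fold. Of 11 flavonoid and anthocyanin genes 9 rose, led by the regulator PAP2 (AT1G66390) at 58.4-fold, with DFR (AT5G42800) at 6.61-fold. Senescence genes followed in part, 6 of 12 rising and 1 falling, with DIN2 (AT3G60140) up 61.4-fold and SAG13 (AT2G29350) up 21.96-fold.

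All listed division genes, most cytokinin genes and part of the cell wall genes went down. All 6 listed mitotic genes fell, for example CYCB1;1 (AT4G37490) 3.24-fold and KNOLLE (AT1G08560) from 27.3 to 10.02 FPKM. Their median log2 ratio was -1.38. Markers of root tissue other than hairs, a list added later, fell in 10 of 12 cases with a median of -1.15. A part played by tissue shares in these falls was not tested. Of 8 type-A response regulators, which report cytokinin signalling, 6 fell and 2 were not called, with ARR7 (AT1G19050) down 9.88-fold and ARR5 (AT3G48100) down 5.53-fold. In the list for cell wall loosening and cellulose 8 of 16 fell, including the expansin EXPA8 (AT2G40610) 29.9-fold and EXPA15 (AT2G03090) 9.42-fold, and XTH23 (AT4G25810) rose 2.59-fold. Photosynthesis genes fell in 9 of 31 cases, with LHCB1.4 (AT2G34430) down 11.6-fold, and 22 were not called.

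Jasmonate genes of the ABA-treated wild type gave 2 rises, 2 falls and 14 without a call, and salicylate and pathogen defence genes 2 rises, PR2 (AT3G57260) 12.7-fold and PR1 (AT2G14610) 9.83-fold, among 13. Aquaporin genes fell in 3 of 13 cases, auxin genes gave 1 rise and 2 falls among 10, and ethylene genes 2 rises and 3 falls among 9, with ORA59 (AT1G06160) down 24.4-fold. Of 8 root and root hair markers 2 fell. The clock genes CCA1 (AT2G46830) and LHY (AT1G01060) rose 7.25-fold and 2.75-fold and LUX (AT3G46640) fell 2.33-fold among 6. Of 5 glucosinolate genes CYP79F1 (AT1G16410) rose 2.71-fold and MAM3 (AT5G23020) fell 4.93-fold, both listed seed storage genes fell (CRA1, AT5G44120, 2.26-fold; CRC, AT4G28520, 3.53-fold), and of both listed DREB factors DREB2A (AT5G05410) rose 2.89-fold and DREB2C (AT2G40340) fell from 2.25 to 0.899 FPKM. The reference gene ACT2 (AT3G18780) was not called, at 588 and 497 FPKM.

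Among genes above 0 in both groups, LTP4 and SWEET15 had the largest rises under ABA in the wild type and DR4 and DIN11 the largest falls. LTP4 (AT5G59310), a lipid-transfer protein gene, rose 919-fold to 2695 FPKM, SWEET15 (AT5G13170), a sugar exporter first described as senescence-associated, rose 539-fold to 529 FPKM, and DR4 (AT1G73330), named for being repressed by drought, fell 79.3-fold from 1741 FPKM. DIN11 (AT3G49620) fell 64.7-fold. The defensin gene PDF1.3 (AT2G26010) fell 59.7-fold, while PDF1.2 (AT5G44420) was listed at 91.3 and 0.434 FPKM without a call. Defensin copies are close in sequence, so the assignment of reads to each copy is uncertain. With 5 FPKM added to every value 654 of the 1185 higher and 481 of the 1839 lower genes were still at least 2-fold apart.

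The duodecuple line answered the same ABA dose with 168 genes called higher and 188 called lower, a comparison that shows which part of the response was left in the mutant. With 5 FPKM added to every value 58 and 38 of them were still at least 2-fold apart. Part of the dehydration genes and most heat shock genes still rose. LEA7 rose 125-fold, but from 0.216 to 26.9 FPKM against 1305 FPKM in the ABA-treated wild type. RD29B (AT5G52300) rose 40.4-fold to 6.83 FPKM against 247, RAB18 24.7-fold to 70.3 FPKM against 1554, and COR15A (AT2G42540) 23.4-fold to 60.4 FPKM against 1192. In all 7 of 18 dehydration genes were called higher, with a median log2 ratio of 1.31 against 4.26 in the wild type. Some large changes of the mutant carried no call. LTP4 went from 0.0498 to 67.5 FPKM, against 2695 FPKM in the ABA-treated wild type. The lipid-transfer-like gene AT2G37870 went from 0.174 to 36.5 FPKM, against 1376 FPKM.

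Heat shock genes of the mutant rose under ABA in 9 of 11 cases, and the other 2 were not called. Their median log2 ratio was 2.92 against 4.83 in the wild type, and between the ABA-treated genotypes it was -3.16. HSFA2 rose 14.1-fold, HSP17.6A (AT5G12030) 11.4-fold to 17.3 FPKM against 296, HSP17.6II (AT5G12020) 8.15-fold and HSP90.1 (AT5G52640) 5.87-fold, and HSP22 was called higher from a control listed at 0 to 4.26 FPKM against 186. SWEET15 rose 48.1-fold to 17.2 FPKM, and with DIN2, at 4.02-fold, and ORE1 (AT5G39610), at 2.71-fold, made up the 3 senescence genes called higher among 12. P5CS1 rose 2.37-fold and GOLS2 2.64-fold, the 2 rises among 10 osmolyte genes. DREB2A rose 2.47-fold, close to its 2.89-fold in the wild type, and CYP79F1 rose 2.53-fold. The seed storage gene CRA1 rose 6.66-fold from 0.105 to 0.698 FPKM, and the aquaporin TIP2;3 (AT5G47450) rose 4.68-fold from 0.745 to 3.49 FPKM. Both had fallen in the wild type, from 4.73 to 2.09 FPKM and from 27.7 to 11.3 FPKM, and stayed lower in the ABA-treated mutant.

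Signalling and growth genes of the duodecuple line were mostly without a call under ABA. Among the 7 clade A phosphatases HAI1 rose 2.51-fold (0.663 to 1.66 FPKM). HAI2 stood at 0.192 FPKM under ABA without a call. HAI3 went from 0.0378 to 0.718 FPKM, a log2 ratio of 4.25, also without a call, so a missing call is not a missing change. None of the 6 SnRK2 genes, 8 ABA metabolism genes, 8 type-A response regulators, 6 mitotic genes, 16 cell wall genes, 11 flavonoid genes, 10 auxin genes, 9 ethylene genes, 6 clock genes or 8 root and root hair markers was called, and of 7 ABA-responsive transcription factors MYB102 alone was, at 2.05-fold. Phosphatase and ABA metabolism genes still had median log2 ratios of 0.73 and 0.42, at the percentiles 99.96 and 99.77 among random lists. SnRK2 genes and the transcription factors had the percentiles 65.4 and 50.4. Root and root hair markers and mitotic genes had median log2 ratios of -0.60 and -0.35, at the percentiles 0.31 and 2.87. Photosynthesis genes fell in 8 of 31 cases, all of them light-harvesting LHCB genes, for example LHCB1.4 4.04-fold and LHCB2.3 (AT3G27690) 3.76-fold. PDF1.2 fell 2.89-fold, the 1 call among 18 jasmonate genes, and CYP71A13 (AT2G30770), a camalexin synthesis gene, fell 2.82-fold, the 1 call among 13 salicylate and defence genes. Among genes above 0 in both groups and at 5 FPKM or more in 1 of them, ATSDI1 (AT5G48850) had the largest fall, 8.39-fold, followed by PCC1 (AT3G22231) at 6.03-fold and PCR1 (AT1G14880) at 5.33-fold.

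Set against each other, the ABA responses of the genotypes overlapped in few genes. Of the 1185 genes called higher in the wild type 114 (9.62%) were called higher in the duodecuple line, and of the 1839 called lower 79 (4.296%) were called lower. The median log2 ratio of those genes in the duodecuple line was 0.28 for the higher and -0.27 for the lower set. Read from the mutant's side, 114 of its 168 higher genes (67.9%) and 79 of its 188 lower genes (42.0%) were called the same way in the wild type. Across the 2103 wild-type called genes used, the ratios of both genotypes correlated with r = 0.64; genes are not independent replicates, and the median of duodecuple over wild-type log2 ratios was 0.15. Across the 218 genes called in the duodecuple line r was 0.81 and that median 0.56, so both values depend on which genotype's calls select the genes. Opposite calls were given to 6 genes higher in the wild type and lower in the duodecuple line and to 12 genes the other way.

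The response difference itself, the duodecuple log2 ratio minus the wild-type one, was computed for 2184 genes called in either genotype under ABA and expressed at 5 FPKM or more. It was at least 2-fold higher for 921 genes and at least 2-fold lower for 724, and was not tested. A higher value can also be a smaller decrease in the mutant, and a lower value a smaller increase. DR4 had log2 ratios of -6.31 in the wild type and -0.64 in the mutant, a 50.8-fold difference. Under ABA 620 FPKM of DR4 remained in the mutant against 21.95 in the wild type. PDF1.2c (AT5G44430) had -8.85, without a call, in the wild type and -2.09 in the mutant, a 109-fold difference. AT4G12580 had the largest opposite value, 49.7-fold, reaching 271 FPKM in the wild type and 8.27 FPKM in the mutant under ABA. IDA (AT1G68765), a peptide gene of organ abscission, followed at 44.3-fold.

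Mannitol changed more genes than ABA in the wild type, a comparison that shows the osmotic response with intact receptors. The authors called 2230 genes higher and 2379 lower, with median log2 ratios of 1.64 and -1.50. Dehydration, pigment, defence and senescence genes rose, and photosynthesis, aquaporin and cytokinin genes fell. Of 18 dehydration genes 17 rose, with a median log2 ratio of 3.79, for example LEA7 145-fold to 798 FPKM, RD29B 89.5-fold and RAB18 67.2-fold to 1368 FPKM. COR15B (AT2G42530) was the exception, at 22.1 and 17.7 FPKM without a call.

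ABA signalling genes rose under mannitol as well. Of the 7 clade A phosphatases 6 rose, HAI3 96.8-fold, HAI2 57.2-fold, HAI1 20.7-fold, ABI2 5.11-fold, ABI1 3.40-fold and PP2CA 2.39-fold, and HAB1 was 1.56-fold higher without a call. Of the 6 SnRK2 genes SNRK2.3, SNRK2.7 and SNRK2.9 rose 2.21-fold, 3.15-fold and 2.27-fold and SNRK2.8 fell 2.33-fold. All 7 ABA-responsive transcription factors rose, HB7 15.2-fold and ABI5 3.38-fold among them. In ABA metabolism 7 of 8 genes rose, including NCED3 5.14-fold, CYP707A1 5.85-fold and ABCG40 4.60-fold. Proline and osmolyte genes rose in 8 of 10 cases, with P5CS1 at 215 FPKM and ALDH7B4 (AT1G54100) up 8.80-fold, and DREB2A rose 3.53-fold. Of 11 heat shock genes 7 rose and HSFA3 fell. HSP22 rose 93.9-fold, whereas HSFA2, at 1.82-fold, and HSP101 (AT1G74310), at 1.19-fold, were not called.

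Salicylate and jasmonate genes were called higher in more cases under mannitol than under ABA in the wild type, a difference that was not tested. Of 13 salicylate and pathogen defence genes 10 rose, with a median log2 ratio of 3.105, such as PR5 (AT1G75040) 39.6-fold to 162 FPKM, PR2 33.7-fold and PAD3 (AT3G26830), the last enzyme of camalexin synthesis, 7.30-fold. Jasmonate genes rose in 11 of 18 cases, among them CORI3 (AT4G23600) 23.6-fold, TAT3 (AT2G24850) 13.04-fold and the repressor gene JAZ8 (AT1G30135) 5.39-fold, and PDF1.2 fell 25.5-fold. Of 11 flavonoid genes 10 rose, against 9 under ABA, PAP2 291-fold, PAP1 (AT1G56650) 43.4-fold and DFR 7.51-fold. Ethylene genes rose in 6 of 9 cases, ACS2 (AT1G01480) 7.27-fold and ERF1 (AT3G23240) 6.16-fold. Of 12 senescence genes 10 rose and DIN10 (AT5G20250) fell, SWEET15 rising 551-fold to 540 FPKM and the chlorophyll breakdown gene PAO (AT3G44880) 6.78-fold. Clock genes rose in 4 of 6 cases, with PRR7 (AT5G02810) at 5.46-fold.

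Photosynthesis genes fell under mannitol in the wild type in 27 of 31 cases, with a median log2 ratio of -1.45, and random lists of like expression had a median of -1.02. RCA (AT2G39730), Rubisco activase, fell 8.07-fold from 3949 to 489 FPKM and RBCS3B (AT5G38410) 8.54-fold. Aquaporin genes fell in 11 of 13 cases, TIP2;1 (AT3G16240) 9.90-fold from 872 FPKM, and PIP2;5 (AT3G54820) rose 2.83-fold. Of 8 type-A response regulators 7 fell, with a median log2 ratio of -2.62, ARR7 14.1-fold. Cell wall genes fell in 10 of 16 cases and rose in 2, auxin genes fell in 6 of 10 and rose in 2, for example IAA3 (AT1G04240) down 7.68-fold and GH3.5 (AT4G27260) up 3.78-fold, and 4 of 6 mitotic genes fell. Root and root hair markers rose in 5 of 8 cases, such as LRX1 (AT1G12040) 3.68-fold and EXPA7 (AT1G12560) 3.41-fold, and the iron transporter gene IRT1 (AT4G19690) fell 3.29-fold at 0.761 FPKM in control. Glucosinolate genes gave 2 rises and 2 falls among 5, neither seed storage gene was called, and ACT2, a reference gene, fell 2.14-fold. Rubisco small subunit, LHCB1 and PIP2 genes have close copies between which reads may be divided.

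Most of the ABA-induced genes of the wild type were also mannitol-induced. Of the 1185 genes called higher under ABA 912 (76.96%) were called higher under mannitol, and of the 1839 called lower 879 (47.8%) were called lower. The shared genes with the largest smaller fold were SWEET15, LTP4 (919-fold and 285-fold), CSLG2 (AT4G24000, 193-fold and 544-fold) and LEA7. Opposite calls went to 5 genes higher under ABA and lower under mannitol and to 69 the other way. Both comparisons used the same control value for each gene, which adds to the overlap by an amount that could not be computed without values per sample.

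In the duodecuple line mannitol still changed a large number of genes, 1572 higher and 1835 lower, the question being what remains of the osmotic response without these receptors. The list medians of jasmonate and salicylate defence genes were higher than in the wild type, and that of dehydration genes was lower. All 18 jasmonate genes rose, with a median log2 ratio of 2.44 against 1.42 in the wild type, for example TAT3 166-fold from 1.22 to 203 FPKM, JAZ8 26.3-fold and LOX2 (AT3G45140) 5.07-fold to 1269 FPKM. Of 13 salicylate and defence genes 12 rose, with a median log2 ratio of 5.07 against 3.105, PR2 86.2-fold, PR1 85.4-fold to 1011 FPKM and FMO1 (AT1G19250) 75.6-fold. ALD1 (AT2G13810), the remaining member, stood 91.9-fold higher without a call. These differences between the genotypes were not tested. Between mannitol-treated genotypes photosynthesis genes, the green tissue markers, had a median log2 ratio of 1.36, against 1.23 for jasmonate and 1.48 for salicylate genes. A part played by tissue shares stays open.

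ABA-linked genes of the mutant rose in part under mannitol. Of 18 dehydration genes 8 rose, with a median log2 ratio of 1.60, COR15A 27.5-fold and RD20 (AT2G33380) 15.3-fold, whereas LEA7 rose 8.01-fold to 1.73 FPKM and RAB18 3.32-fold to 9.45 FPKM. Of the 7 clade A phosphatases ABI1 rose 2.11-fold, ABI2 2.42-fold and HAI1 2.64-fold, and HAI2, HAI3, HAB1 and PP2CA were not called, at 0.389, 0.110, 21.6 and 16.8 FPKM. No SnRK2 gene was called. Transcription factors rose in 4 of 7 cases, HB7 4.55-fold and ABI5 2.94-fold among them. In ABA metabolism NCED3 rose 10.5-fold to 5.88 FPKM, ABCG40 43.6-fold and BG1 (AT1G52400) 6.83-fold, and the other 5 were not called. Osmolyte genes rose in 7 of 10 cases, P5CS1 10.96-fold to 152 FPKM and GOLS2 28.1-fold, and the proline-degrading PRODH1 (AT3G30775) fell 4.76-fold to 47.8 FPKM, a gene not called in the wild type at 374 FPKM. Heat shock genes gave 4 rises and 1 fall among 11, both DREB factors rose, and senescence genes rose in 10 of 12 cases, SAG13 49.9-fold, while SWEET15 rose 4.16-fold to 1.49 FPKM.

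Growth and tissue genes of the mutant under mannitol partly followed the wild type. All 8 type-A response regulators fell, ARR3 (AT1G59940) 9.13-fold, and aquaporin genes fell in 10 of 13 cases, TIP2;1 14.7-fold. Photosynthesis genes fell in 4 of 31 cases and rose in 1, RCA 2.45-fold lower at 1465 FPKM and LHCB1.5 (AT2G34420) 2.37-fold higher, with a list median of -0.43 against -1.45. Cell wall genes gave 4 rises and 5 falls among 16, XTH17 (AT1G65310) falling 28.8-fold and EXPA1 (AT1G69530) rising 3.29-fold. Root and root hair markers fell in 5 of 8 cases, PRP3 (AT3G62680) 5.25-fold and RHS18 (AT5G22410) 6.13-fold. Flavonoid genes rose in 6 of 11 cases and FLS1 (AT5G08640) fell 2.76-fold. Ethylene genes rose in 6 of 9 cases, ERF1 23.5-fold. Auxin genes gave 1 rise and 3 falls among 10, mitotic genes 4 falls among 6, clock genes 2 rises among 6, and glucosinolate genes 1 rise and 2 falls among 5. CRA1 rose 22.9-fold from 0.105 to 2.41 FPKM. ACT2 was not called. Among genes above 0 in both groups the largest changes included TPS04 (AT1G61120), a terpene synthase, up 338-fold, NATA1 (AT2G39030) up 317-fold, and the lipid-transfer-like gene AT5G46900 down 102-fold.

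**Figure D2:**
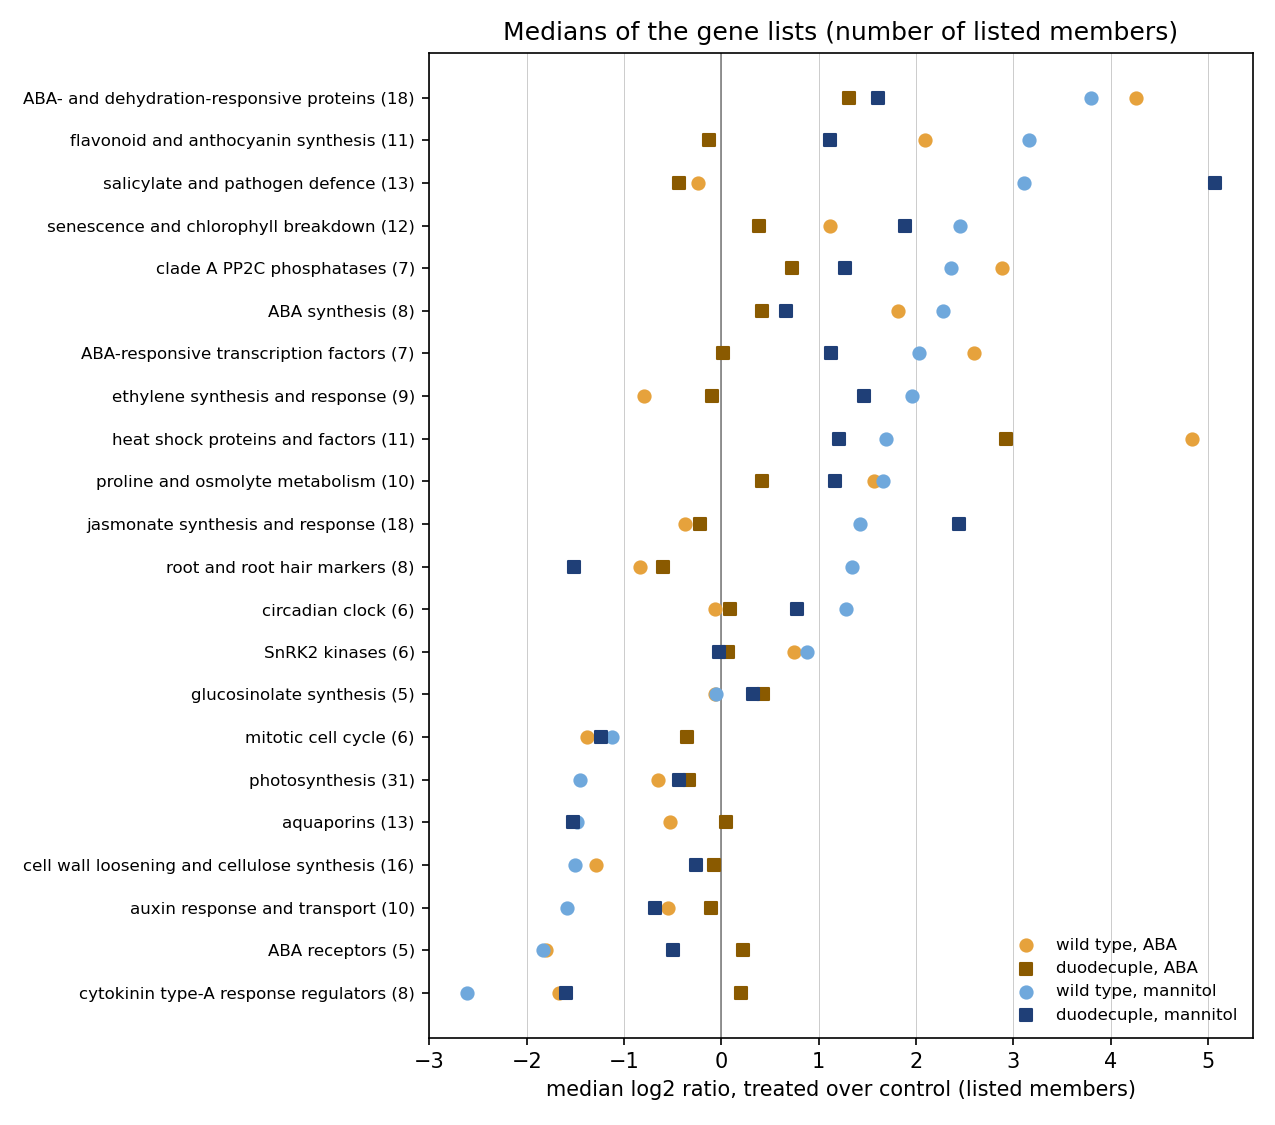
Median log2 ratio, treated over control, of the listed members of 22 gene lists, with the number of listed members in parentheses; circles are the wild type, squares the duodecuple line, orange and brown ABA, light and dark blue mannitol. Dehydration genes sit at 4.26 and 3.79 in the wild type and at 1.31 and 1.60 in the duodecuple line, and salicylate genes at 3.105 and 5.07 under mannitol.

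Under mannitol the genotypes shared a large part of their calls. Of the 2230 genes called higher in the wild type 1017 (45.6%) were called higher in the duodecuple line, and of the 2379 called lower 1029 (43.3%) were called lower, with median log2 ratios there of 0.99 and -0.91 over all of them. The shared genes with the largest smaller fold were CSLG2, DXPS1 (AT3G21500), GPT2 (AT1G61800, 100.1-fold in the wild type), TPS04 and PR5 among the rises, and AT5G46890, AT4G12510 and AT5G46900 among the falls. Genes called in the duodecuple line alone numbered 534 higher and 741 lower. Their wild-type median log2 ratios were 0.65 and -0.51, and 55.1% and 44.9% of them were at least 1.5-fold changed in the same direction in the wild type. The authors also deposited 2 selected lists of such genes, of 555 and 720 members; 21 of the 555 members of the list of induced genes are listed at 0 under mannitol, and are lower, among them PYL12, XTH26 (AT4G28850) and AT5G27889.

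**Figure D3:**
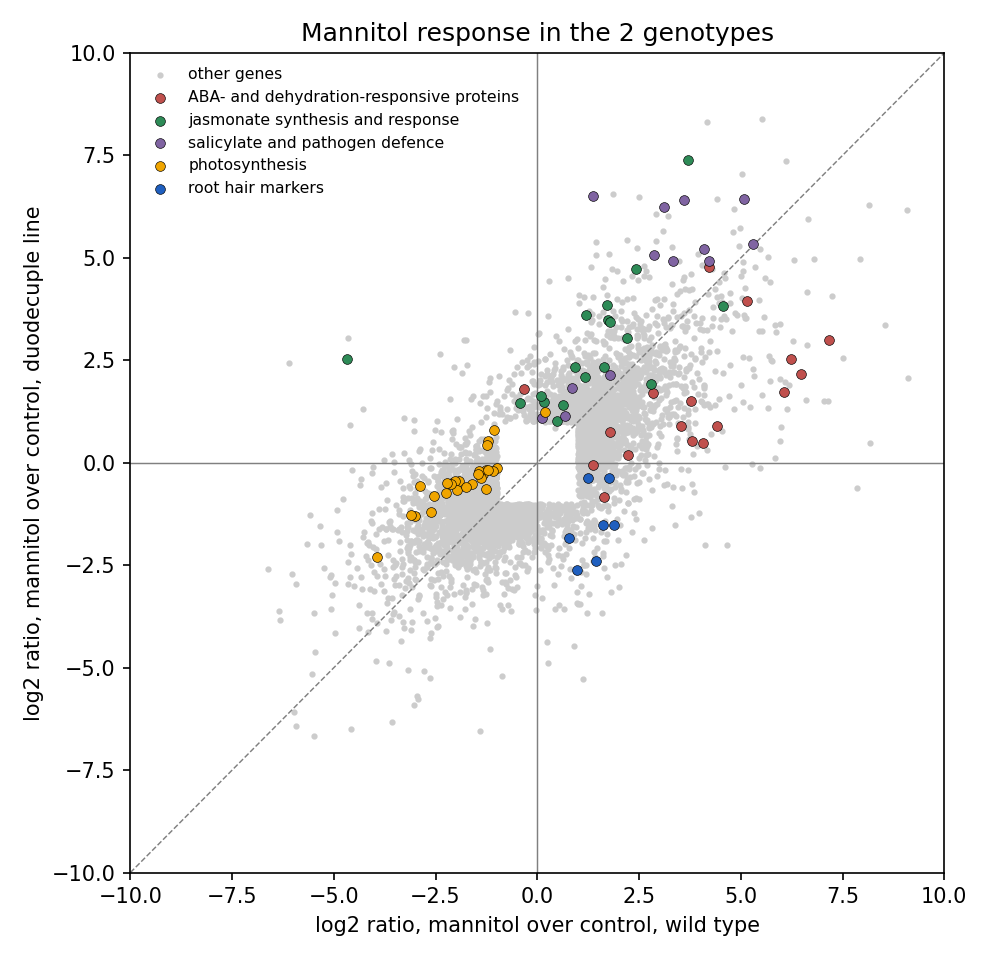
Log2 ratio of mannitol over control in the wild type (horizontal) and the duodecuple line (vertical) for 5766 genes with finite ratios that were called under mannitol in either genotype; colours mark members of 5 gene groups and the dashed line equal ratios. Jasmonate and salicylate genes lie mostly above the line and dehydration genes mostly below it, and all 7 root hair markers are above 0 in the wild type and below 0 in the duodecuple line.

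Opposite calls under mannitol fell on root hair markers, among other genes. The 65 that rose in the wild type and fell in the duodecuple line included the root hair markers PRP3 (40.5 FPKM against 4.196 under mannitol), EXPA18 (AT1G62980, 19.7 against 3.34) and LRX1 (7.85 against 1.29), and 8 carry extensin in the deposited description. The 21 that fell in the wild type and rose in the mutant included the defensins PDF1.2, PDF1.2b (AT2G26020), PDF1.2c and PDF1.3, the expansins EXPA1 and EXPA8, and the aquaporin PIP2;3 (AT2G37180). PDF1.2 stood at 3.58 FPKM in the wild type and 2387 FPKM in the mutant under mannitol. Response differences, over 4404 genes, were at least 2-fold higher in the mutant for 804 and lower for 854. Here too a higher value can be a smaller decrease and a lower value a smaller increase. Among the lower ones CCD8 (AT4G32810), a strigolactone synthesis gene, had 107 FPKM in mannitol-treated wild type and 0.582 FPKM in the mutant, a 356-fold difference in response. PAP2 followed at 206.5-fold, with 29.9 FPKM in mannitol-treated wild type and 3.11 FPKM in the mutant. Its control values were 0.103 FPKM in the wild type and 2.21 FPKM in the mutant, so the higher untreated level of the mutant enters that difference. Extensin-like and defensin copies share sequence, so the single-gene values are uncertain.

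Mannitol-induced genes that ABA also induced in the wild type, and those without an ABA call, had like medians in the mutant. Their medians in the wild type lay further apart. The 912 genes called higher under both had a median mannitol log2 ratio of 2.11 in the wild type and 0.99 in the duodecuple line, where 44.3% were called higher. The 1249 genes called higher under mannitol without an ABA call had medians of 1.41 and 0.95, and 44.6% were called. The 69 mannitol-induced genes that ABA lowered had medians of 1.51 and 1.85, and 81.2% were called in the mutant. Among the falls, 879 genes lowered by both treatments had medians of -1.77 and -1.30 with 61.1% called, and the 1495 without an ABA call had -1.41 and -0.77 with 32.7% called.

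Control seedlings of the genotypes differed in phosphate-starvation, pigment and dehydration genes, among others. Of 4226 genes with 5 FPKM or more in the higher group, 229 were at least 2-fold higher in the duodecuple line and 172 at least 2-fold lower. The lipid synthase gene MGD3 (AT2G11810) was listed at 19.9 FPKM against 0.195, 102-fold higher, and IPS1 (AT3G09922), a phosphate-starvation RNA, at 18.6 against 0.323, 57.5-fold higher. PECP1 (AT1G17710) was 24.9-fold and SPX3 (AT2G45130) 22.4-fold higher. In the fixed lists the 11 flavonoid genes had a median log2 ratio of 1.42, with LDOX (AT4G22880) at 71.2 FPKM against 23.3. The 18 dehydration genes had a median of -1.65 and the 7 clade A phosphatases one of -1.17. Heat shock, ABA metabolism and aquaporin genes had medians of -0.87, -0.82 and -0.64, each at the percentile 0.03 or lower among random lists. AT2G25450, an oxygenase-like gene, was 54.3-fold lower at 6.29 against 341 FPKM, the marneral synthase gene MRN1 (AT5G42600) 52.4-fold lower, TIP2;3 37.2-fold lower and LEA7 25.6-fold lower.

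With ABA the genotypes lay further apart, 975 genes at least 2-fold higher and 929 at least 2-fold lower in the duodecuple line among 4336. Only genes called under a treatment were analysed, 3024 of the 6740 under ABA in the wild type, which favours wider gaps in treated seedlings. HAI2 was 176-fold, HAI3 121-fold and the heat shock factor gene HSFA6A (AT5G43840) 225-fold lower, the last at 0.0725 FPKM against 16.3. PDF1.2 was 328-fold and PDF1.2c 468-fold higher. The dehydration genes had a median log2 ratio of -4.39 and the phosphatases one of -3.33, while the 16 cell wall genes had one of 1.32.

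With mannitol 754 genes were at least 2-fold higher and 948 at least 2-fold lower in the duodecuple line among 4396. LEA7 was 463-fold and SWEET15 364-fold lower, and AT2G25510, listed at 602 FPKM in the wild type and 0.171 in the mutant, 3513-fold lower. PDF1.3 was 1427-fold higher. List medians were -3.60 for dehydration genes, -2.27 for root and root hair markers, 1.23 for jasmonate genes, 1.48 for salicylate genes and 1.36 for photosynthesis genes. Without the minimum of 5 FPKM, or with 5 FPKM added to each value, several of these counts of genotype ratios changed by more than 1.5 times.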

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

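The gene lists, the rule for named genes, the comparisons and most alternatives were chosen before the data were examined. Chosen after the data had been seen were the pseudocount of 1 for the calls, all settings for the ABA overlap of the genotypes, all settings for the genotype ratios, and the minimum of 5 FPKM for the split of mannitol genes by ABA call. Of 94 alternatives for 30 results, 56 stayed within 1.5 times the main value and 38 moved further; with no values per library, 1.5 times was the measure for every value. The causes were not tested beyond the fact that a stricter setting leaves fewer genes.

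Low values carried much of each count. With a pseudocount of 5 FPKM, genes called higher and lower and still 2-fold apart numbered 654 and 481 for wild-type ABA, 1144 and 1047 for wild-type mannitol, 58 and 38 for duodecuple ABA, and 734 and 547 for duodecuple mannitol. A pseudocount of 1 left 1179 lower genes for wild-type ABA and 109 higher and 74 lower for duodecuple ABA. A minimum of 5 FPKM left 989 lower genes for wild-type ABA, 102 higher and 87 lower for duodecuple ABA, and 1143 lower for duodecuple mannitol.

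Overlaps shrank in the same way. At 4-fold in both, the genotypes shared 301 higher and 172 lower genes under mannitol and 34 and 8 under ABA, and wild-type ABA and mannitol shared 308 and 202. With a minimum of 5 FPKM these were 666 lower for mannitol, 71 higher and 38 lower for ABA, and 525 lower for ABA with mannitol.

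Genotype ratios of 2-fold or more numbered 516 higher and 417 lower in control seedlings without a minimum and 99 and 67 with a pseudocount of 5. Under ABA they numbered 1952 higher without a minimum and 542 with the pseudocount, and under mannitol 1220 higher without a minimum and 453 higher and 628 lower with the pseudocount. Response differences numbered 1453 higher under ABA without a minimum and 390 with the pseudocount, and 433 higher and 526 lower under mannitol with it. None of 220 named gene ratios changed sign under pseudocounts of 0.1 and 5. Adding the same value to both groups cannot change a sign, so this says nothing about the directions. At 0.1 FPKM 86 of 110 stayed within 1.5-fold and at 5 FPKM 10 of 110, so folds of genes near 0 in either group are loose.

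No paired analysis was possible because the tables hold 1 value per group and none per library. For the same reason the other normalization (DESeq2), the replicate block, leaving out single libraries, fits on fewer samples and an adjusted p limit of 0.01 were not run. Depth is unknown.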

Other observations

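The test on the share of root tissue between the genotypes, the extra lists and the check on genes picked from control seedlings alone were chosen after the result was seen; the other tests were set down before their values were computed, from hints in the largest genotype differences and in the opposite calls under mannitol. The rule for root tissue in the mutant was first coded otherwise than it had been written, and putting it right after its value had been seen changed its label from cannot tell to fits. Also picked after their values were seen were LSU1, LSU3 and ATSDI1, known from work on sulfur shortage; no list of such genes was tested. LSU1 (AT3G49580) was listed at 161 FPKM in the duodecuple control against 14.5 in the wild type, LSU3 (AT3G49570) at 77.2 against 8.73, and ATSDI1 (AT5G48850) at 116 against 11.1. After ABA they fell in the mutant to 36.0, 16.3 and 13.8 FPKM, and after mannitol they stood at 168, 107 and 94.3 FPKM without a call. In the wild type ABA lowered LSU3 to 2.23 and ATSDI1 to 5.22 FPKM, and LSU1 was not called. Among the 12 genes that ABA lowered in the wild type and raised in the mutant, named after their values were seen, were the glutathione transferase genes GSTU25 (AT1G17180) and GSTU22 (AT1G78340), with 10.6 and 4.84 FPKM against 89.3 and 16.2, and the zinc transporter gene ZIP2 (AT5G59520), with 3.23 against 20.5.

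Placed among random lists of table genes, salicylate genes had the percentile 100 under mannitol in both genotypes, and dehydration genes had it under ABA in both. Photosynthesis genes in mannitol-treated wild type had the percentile 0.315, but lists of like expression had a median of -1.02 themselves, so abundant genes of the table went down as a whole. In the mannitol-treated duodecuple line the photosynthesis percentile was 38.8. Markers of root tissue other than hairs fell in 10 of 12 cases under ABA in the wild type, for example CASP2 (AT3G11550) 6.58-fold, and none was called in the ABA-treated mutant.

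Phosphate-starvation genes were raised in untreated mutant seedlings. Of a list of such genes written after IPS1, MGD3, PECP1 and SPX3 had been seen among the largest differences, the 10 other listed members had a median log2 ratio of 2.45, with 9 of 10 higher, and the highest median of 10000 random lists was 0.797. SPX1 (AT5G20150) was listed at 139 against 9.17 FPKM and PPSPASE1 (AT1G73010) at 29.5 against 2.01. The 14 listed among the 21 members of the list had medians of 3.097 in control, 1.65 with ABA and 0.93 with mannitol. With mannitol 9 rose and 1 fell in the wild type and 1 rose and 6 fell in the mutant. Only genes with a call were listed, and the control values enter both the calls and the untreated ratio. What this selection adds to the medians was not tested. A raised phosphate-starvation programme in the mutant is a candidate explanation; plates, medium or seedling size that differed between the genotypes stay open and were not tested.

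Root hair markers moved apart under mannitol. The intervals below are over marker genes and hold no error between libraries. Of 8, 7 were listed, with a median log2 change of 1.445 in the wild type (95% interval 0.97 to 1.77; 5 rose) and -1.53 in the mutant (-2.39 to -0.36; 5 fell). Markers of other root tissue had a median of -0.89 in the wild type (-2.14 to -0.28), not the rise that more root tissue would give. In the mutant these markers had -1.10 (-1.87 to -0.40). Fewer root cells could thus account for the mutant's fall from its own control, with an interval that leaves the size open. Between the genotypes under mannitol, other root tissue differed by 0.048 on the log2 scale (-0.72 to 0.44). Root hair markers differed by -2.56 (-3.096 to -1.49). Under ABA root hair markers had median log2 changes of -0.77 in the wild type and -0.61 in the mutant, where none was called. However, ABA alone lowered 10 of the 12 other markers in the wild type and none was called in the mutant. With ABA their median log2 ratio of mutant over wild type was 1.25. Such a fall in the wild type could mask a larger share of root tissue there, so these markers cannot decide on unequal shares. Photosynthesis genes, the markers of green tissue, had a median of 1.36 between the genotypes under mannitol (random lists 0.37), which a larger share of green tissue in the mutant would also give, so a part played by tissue shares stays open. An effect on hair cells stays a hypothesis, and reads shared among extensin-like genes were not tested.

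Some genes differed between the genotypes whatever the treatment. There were 67 at least 4-fold apart in all 3 with 1 FPKM or more in the higher group each time, 24 higher and 43 lower in the mutant. Sequence of another strain left around the mutated loci predicts clusters there. Of the 67 genes, 3 lay within 100 loci of the 11 receptor genes other than PYL2. The median was 4 over 6713 shifts of the labels. This argues against such sequence within 100 loci of these 11 genes as the main source of the 67 genes. Longer segments would reach beyond that window and are not covered. A segment at a single locus is not excluded by this pooled count. Strain differences in genes without a treatment call were not analysed. At PYL2 itself 3 of 50 listed genes were among them (AT2G25450, AT2G25510 and AT2G25890), as many as in 0.968% of shifts, but the idea came from the first pair of these, so a linked strain segment at PYL2 may remain. Loss of ABA signalling was weighed by direction: 94.0% differed opposite to their wild-type ABA change, against 56.2% of other genes, but picking genes by their ABA-treated values favours this. Among 170 picked on control seedlings alone the share was 63.5%, but that choice favours the reverse, because the wild-type control value enters both ratios. Neither share measures the effect of the selection, and the explanation stays open.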
